A study of Mus musculus with 6 samples.

How the data were processed

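RNA sequencing was done on 6 hippocampus samples labelled as male wild-type mouse at 21 days, 3 in the control group given 0 mg/kg/day and 3 in the group given 1.5 mg/kg/day of F-53B, which the sample titles call High. Per the labels' protocols, total RNA was extracted with FreeZol reagent, and 1.5 µg of it went into libraries made with the KC-digital mRNA kit. Whether counting used strand or molecular identifiers, and how reads that map to several places were treated, is not given in the sources used here. Group and replicate number were taken from the sample titles, and all 6 samples were mapped. The series title and design text name another compound, methyl ester sulfonate, and speak of exposure into adulthood; the sample titles name F-53B and the labels give an age of 21 days. The groups are therefore named here by the sample titles, and the compound is uncertain to that extent.

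The authors deposited a table of raw read counts per gene for 56791 genes, with gene symbols, coordinates and gene lengths. They also deposited a table of RPKM values, which scale counts by gene length and library total, for 36734 genes. The processing notes of the submitters name Trimmomatic 0.36, featureCounts, Subread 1.5.1, edgeR 3.12.1 and the mouse build mm10; which step used which is not given in the sources used here, and neither are the aligner and its settings. The deposited counts were whole numbers with different totals in each library. The deposited RPKM values equalled the count divided by gene length and by the library's total count within a relative tolerance of 1e-06, so they carry no further normalization. The 20057 genes absent from the RPKM table had no count in any library. Each gene entry had a name, so no counts were set aside before the totals were formed.

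Coordinates are printed as the count table gives them, from 1. They are not mm10 coordinates: of 48988 symbols that matched 1 gene of the GENCODE M21 annotation of mm10, 48986 were on the same chromosome but 1342 had the same start and end. Xkr4, for example, began at position 3276124 of chromosome 1 in the table and at 3205901 in mm10. No build is therefore named for the printed positions. The mm10 annotation was used only for this comparison, for gene types matched by symbol and for GC content. Overlap of exons between neighbouring genes was taken from the positions in the count table.

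Total counts were 50841656, 48875218 and 39365581 in Control replicates 1, 2 and 3 and 56461623, 46950942 and 46953377 in F-53B replicates 1, 2 and 3. A floor of 3 counts corresponds to 0.059, 0.0614 and 0.0762 CPM (counts scaled to a common library total) in the Control libraries and 0.0531, 0.0639 and 0.0639 CPM in the F-53B libraries, in the same order. Such floors cover counting error only, since reads are not independent molecules. No pair of replicates agreed within sampling noise: chi-square per degree of freedom between libraries of a group, over genes with a mean count of at least 50, ran from 10.1 to 49.8, so each library was counted once.

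The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and F-53B was compared with Control by the quasi-likelihood test with no covariate, followed by Benjamini-Hochberg adjustment over all 21324 tested genes, with a threshold of 0.05. Fold changes are log2 of F-53B over Control. Their standard error (SE) was derived as the absolute fold change divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled totals and are given as mean ± SD of 3 libraries. Log2 CPM values in the list scores per library carry a prior count of 2. Such a score is the median over a list's tested genes of each gene's log2 CPM minus its mean in the Control libraries, and scores were compared by a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries in each group.

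Groups of genes were 34 lists of hippocampal cell types, neighbouring tissues, pathways and gene families. Each list was tested against all other genes with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. The test was repeated with a correlation estimated for each list, and with fry. The PValue of fry tests whether the genes of a list move, on balance, one way, and its PValue.Mixed tests whether they change in either direction; neither compares a list with other genes. Counts of members past the threshold were made over all tested genes and adjusted over the list alone. The lists of Notch signal genes and of Hes and Hey genes come from the title of the series, so they may not be independent evidence of a direction in these samples. The list symbols Nlgn4l, Pvrl3, Hbb-b1 and Hbb-b2 were not matched by symbol in the count table.

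The genes named in the text follow a rule. They are the 12 higher and 12 lower genes of smallest p among those past the threshold whose 3 F-53B values lie all above or all below the 3 Control values, leaving out predicted gene models. Named in every case are Notch1, Notch2, Notch3, Dll1, Dll3, Jag1, Hes1, Hes5, Hes6, Hey1, Hey2 and Rbpj. From each list come up to 4 members of smallest p where a member or the list passed, and otherwise at most 2. Other genes outside the rule are marked where they appear as chosen after their values were seen. Xist, Ddx3y, Xkr4, mt-Co2, mt-Co3, mt-Atp6 and neighbours with shared exons also lie outside the rule and carry no such mark. The lists, the naming rule, the test and 23 alternatives were chosen before the data were examined.

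The alternatives were DESeq2 1.42.0, the exact test of edgeR, limma-voom, RLE size factors and library totals in place of TMM, no filter and a filter at a mean CPM of 1, the replicate number as a block, other thresholds, limma on log2(RPKM + 0.1) and log2(RPKM + 1) with a filter at a mean RPKM of 0.1 or none, set tests with an estimated correlation or fry, and leaving out each library in turn. The choroid plexus score and the thalamus score as covariates, and set tests with an estimated correlation in each refit, were added after the data were seen.

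The fit was tested on simulated data, with counts of 21019 genes drawn from the means and spread of these libraries and 200 genes of at least 50 counts changed by known factors. For F-53B against Control it recovered 14% of genes changed 1.3-fold, 48% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 50 genes at each size. It called 135 genes in all, of which 9 were unchanged. In the same simulation camera gave an unadjusted p under 0.05 to 4 of 200 random lists and 2.89e-36 to a list of genes made lower. Random lists need not share the correlation of real lists, estimated at 0.477 for astrocyte and 0.936 for myelin genes. The simulation therefore does not show how camera at the preset correlation performs on such lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Splicing, transcript isoforms and sequence variants were not analysed here. Some genes that the naming rule picks are not reported here.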

Results

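Hippocampal RNA was sequenced in samples labelled as young male mice, from a control group (n = 3) and a group given F-53B at 1.5 mg/kg/day (n = 3), the only dose besides 0 mg/kg/day in these samples. F-53B is a chlorinated polyfluoroalkyl ether sulfonate used as a mist suppressant in chrome plating. The series title and design text name methyl ester sulfonate, a detergent surfactant, in its place, and describe exposure through drinking water from the embryonic stage, so the compound is given here as the sample titles give it. The labels number 3 samples in each group without saying that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

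Total counts per library ranged from 39365581 to 56461623, and between 28510 and 29939 genes had a count. The 10 most abundant genes took 8.21%, 7.98% and 7.61% of the counts in Control replicates 1, 2 and 3 and 7.68%, 7.82% and 6.64% in F-53B replicates 1, 2 and 3. Mitochondrially encoded genes took 5.27%, 5.39% and 4.95% in the Control libraries and 4.93%, 4.87% and 3.86% in the F-53B libraries. The female-specific transcript Xist had 350 counts in F-53B replicate 1 against 48, 44 and 30 in the Control libraries and 65 and 54 in F-53B replicates 2 and 3, while the Y-linked gene Ddx3y had between 2313 and 3108 counts in all 6 libraries. Pearson correlations of log2 CPM across genes lay between 0.9853 and 0.991 for libraries of a group and between 0.9845 and 0.9898 across groups. The first principal component, with 31.4% of the variance, placed the Control libraries at -13.1, -19.7 and -25.9 and the F-53B libraries at -5.8, 24.1 and 40.4.

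The comparison asks which hippocampal transcripts differed between exposed and control animals. In the F-53B group, Fabp7, a fatty acid binding protein of radial glia and astrocytes, rose from 36.5 ± 5.09 to 74.2 ± 8.58 CPM (SD, n = 3). Fam107a, an actin-associated protein of astrocytes and radial glia, fell from 674 ± 51.9 to 295 ± 8.84 CPM. Hes1, a transcriptional repressor induced by Notch, rose from 5.14 ± 0.159 to 8.25 ± 0.703 CPM, while Notch1 did not pass the test at 20.3 CPM in Control and 15.1 CPM in F-53B. Most calls were lower in F-53B: of 21324 genes tested, 17 rose and 138 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test), among them 1 higher and 46 lower genes with a change of at least 1 log2 unit. All 155 had non-overlapping groups, as did 20.4% of the tested genes against 10% by chance, and 3006 genes (14.1%) had an unadjusted p under 0.05. Predicted gene models made up 1 of the higher and 19 of the lower calls. The count varied with the library left out. It was 48, 48 and 49 without Control replicates 1, 2 and 3. Without F-53B replicates 1, 2 and 3 it was 448, 21 and 145, the last with 35 higher. All 155 genes kept their sign in each of these fits, which non-overlapping groups all but fixed in advance. F-53B replicate 1 had the higher Xist count. Its choroid plexus score (-0.02) also lay above those of F-53B replicates 2 and 3 (-1.70 and -1.85), as did its thalamus score (0.57 against -1.32 and -0.84). Which of these traits, if any, bears on the count was not tested.

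Among the higher genes, Fabp7 (chromosome 10, 57660977 to 57664546) had a log2 fold change of 1.02 ± 0.11 (SE, edgeR adjusted p = 0.00439), and it was the only named higher gene called without each of the 6 libraries. In the limma fits of RPKM values its call was lost (adjusted p = 0.061, 0.0676 and 0.098). Cck, the cholecystokinin neuropeptide, rose by 0.51 ± 0.06 (adjusted p = 0.00751), from 55.2 to 78.7 CPM, and lost its call without Control replicate 2 (adjusted p = 0.0521) or F-53B replicate 2 (adjusted p = 0.0658). Crym, a thyroid hormone binding protein, rose by 0.44, and Opcml, a cell adhesion molecule of neurons, by 0.37. The heparan sulfate modifying enzyme Ndst4 rose by 0.64, the GTPase regulator Elmod1 by 0.35, the septin Septin6 by 0.46 and the ephrin Efna3 by 0.51. Atp6v1g2, a subunit of the vacuolar proton pump, rose by 0.34, Sez6, a neuronal membrane protein of synapse maturation, by 0.48, and Slc16a1, a monocarboxylate transporter, by 0.48. Adjusted p for Crym to Slc16a1 lay between 0.0198 and 0.0395, and the median of all 17 higher calls was 0.48. Those from Crym to Slc16a1 lost their calls without Control replicate 1 (adjusted p from 0.0724 to 0.139), Control replicate 3 (0.0706 to 0.147) or F-53B replicate 2 (0.072 to 0.204). Without Control replicate 2 all but Ndst4 (0.0424) did (0.0753 to 0.158), and without F-53B replicate 3 Sez6 did (0.059).

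Among the lower genes, Fam107a (chromosome 14, 14151750 to 14173499) had a log2 fold change of -1.19 ± 0.07 (adjusted p = 0.000212), the smallest p of all genes. Prodh, the mitochondrial proline dehydrogenase, fell from 80.4 to 38.7 CPM (-1.06, adjusted p = 0.00111). The metallothionein Mt2 fell from 31.1 to 15.4 CPM (-1.01), a value that is uncertain because 73.5% of its exonic length is shared with the opposite-strand gene model Gm45774. Glul, the glutamine synthetase of astrocytes, fell from 640 to 406 CPM (-0.66 ± 0.07, adjusted p = 0.00439). Further lower genes were the sulfotransferase Sult1a1 (-1.43), the PDZ protein Pdzd2 (-0.75), the matrix Gla protein Mgp (-1.15), the adhesion molecule Kirrel2 (-1.39), the ciliary tektin Tekt4 (-2.04), the acyl-CoA thioesterase Acot11 (-0.92), the Rac exchange factor Prex2 (-0.85) and the membrane-cytoskeleton linker Ezr (-0.77). Of the exonic length of Acot11, 20.9% is shared with Fam151a. All 12 of these lower genes, and the growth factor receptor Fgfr3 described with the astrocytes, kept their call without each of the 6 libraries, and the median of the 138 lower calls was -0.82. In the limma fits of RPKM values Fam107a, Prodh and Mt2 passed in all 3, Fgfr3, Pdzd2 and Prex2 in 0 (adjusted p from 0.0538 to 0.0969), and the others lost their call in at least 1.

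**Figure D1:**
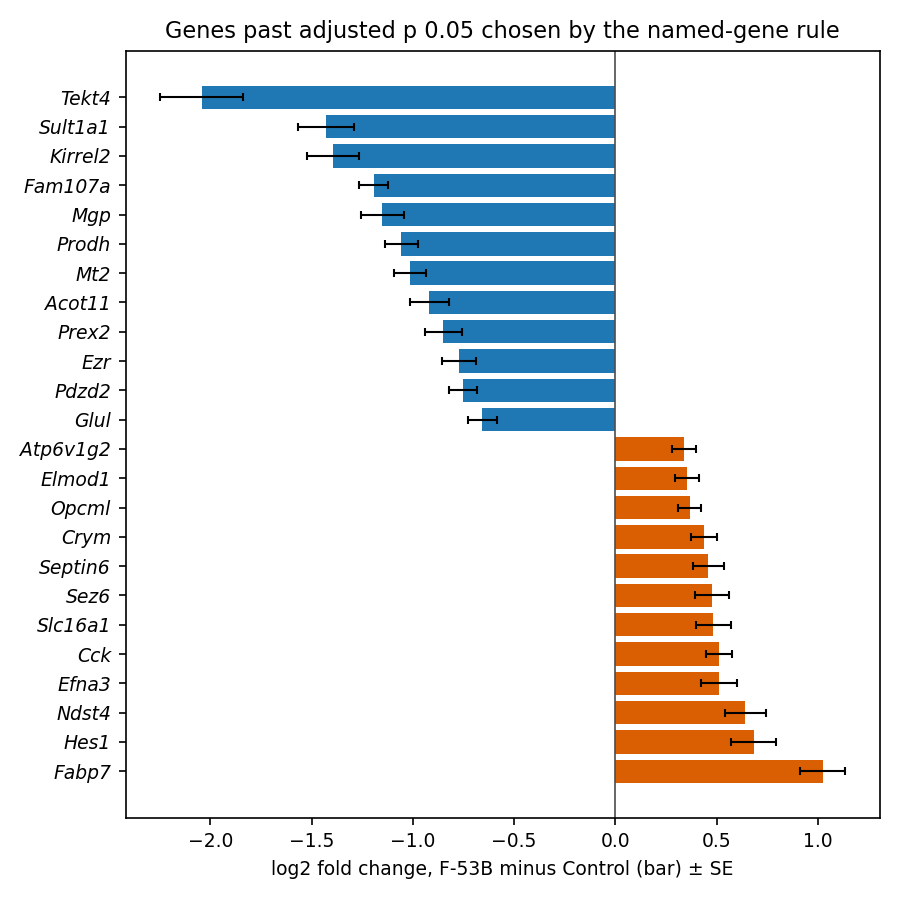
Log2 fold change of F-53B over Control hippocampus for the 12 higher (orange) and 12 lower (blue) named genes, n = 3 libraries in each group, bars with whiskers of 1 SE from the edgeR fit. Changes run from -2.04 for Tekt4 to 1.02 for Fabp7, and Hes1 stands at 0.68.

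The title of the series points to Notch and Hes genes. Hes1 (chromosome 16, 29883202 to 29886614) had counts of 263, 245 and 206 in the Control libraries and 435, 424 and 376 in the F-53B libraries, a log2 fold change of 0.68 ± 0.11 (edgeR adjusted p = 0.0317). Hes5, another Notch-induced repressor, stood at 1.15 CPM in Control and 1.81 CPM in F-53B (0.66 ± 0.26, adjusted p = 0.288); 31.8% of its exonic length is shared with the opposite-strand gene model Gm20421. The receptors Notch1 (-0.43 ± 0.12, adjusted p = 0.152), Notch2 (-0.32, adjusted p = 0.156) and Notch3 (-0.43, adjusted p = 0.302) were below Control in all 3 F-53B libraries without passing the test, as were the target Hey2 (-0.48, adjusted p = 0.174) and the DNA-binding partner Rbpj (-0.26, adjusted p = 0.255). The ligand Dll1 (0.33, adjusted p = 0.209) lay above Control in all 3. Overlapping groups were found for Dll3 (0.10, adjusted p = 0.953), Jag1 (-0.26, adjusted p = 0.407), Hes6 (0.10, adjusted p = 0.791) and Hey1 (0.10, adjusted p = 0.61). The call for Hes1 was lost without Control replicate 1, 2 or 3 (adjusted p = 0.121, 0.127 and 0.103) and without F-53B replicate 2 (adjusted p = 0.187), with fold changes between 0.61 and 0.73 over the 6 leave-outs. Notch1 passed with DESeq2 (adjusted p = 0.0378), the range over its leave-outs being 0.0884 to 0.415. With no filter on low counts Notch1 (adjusted p = 0.00524) and Notch3 (adjusted p = 0.0339) passed.

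Taken as groups, neither list from the title passed camera or the test of fry for 1 direction. Both were among the 22 of 34 lists that by fry held genes changed in either direction (adjusted p = 0.0043 and 0.0007). That test does not compare a list with other genes. Of 39 tested Notch ligands, receptors and signal components, 0 rose, 0 fell and 39 did not pass, and adjusted over the list alone 1 fell, the glycosyltransferase Lfng (-0.60, adjusted p over all genes = 0.057); Notch4 had -0.59. Without F-53B replicate 1, 1 member fell, and with no filter on low counts 5 did. The camera adjusted p was 0.205 (adjusted p = 0.592 with an estimated correlation), with a median of -0.04. Of 17 tested Hes, Hey and other Notch target genes, 1 rose (Hes1) and 16 did not pass; adjusted over the list alone 1 rose and 2 fell, Id4 (-0.30) and Hey2. Another member, Nrarp, had -0.30, a value that is uncertain because 79.4% of its exonic length is shared with the opposite-strand gene model Gm38287. The camera adjusted p was 0.671 (adjusted p = 0.815 with an estimated correlation). Both lists come from the study's title, so they may not be independent evidence of direction. Among 26 proneural factors and markers of immature neurons, 0 passed over all genes, and adjusted over the list alone 3 rose and 2 fell, with Tubb3 at 0.33 and Neurod2 at 0.37. The median was 0.01, the mean -0.04 and the test downward (camera adjusted p = 0.773). Of 26 genes of neural stem cells and proliferation, Fabp7 rose and 25 did not pass, and adjusted over the list alone Fabp7 rose and Vim (-0.47) fell, with camera adjusted p = 0.633 and Ccna2 and Cdk1 at 0.23 and 0.64.

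**Figure D2:**
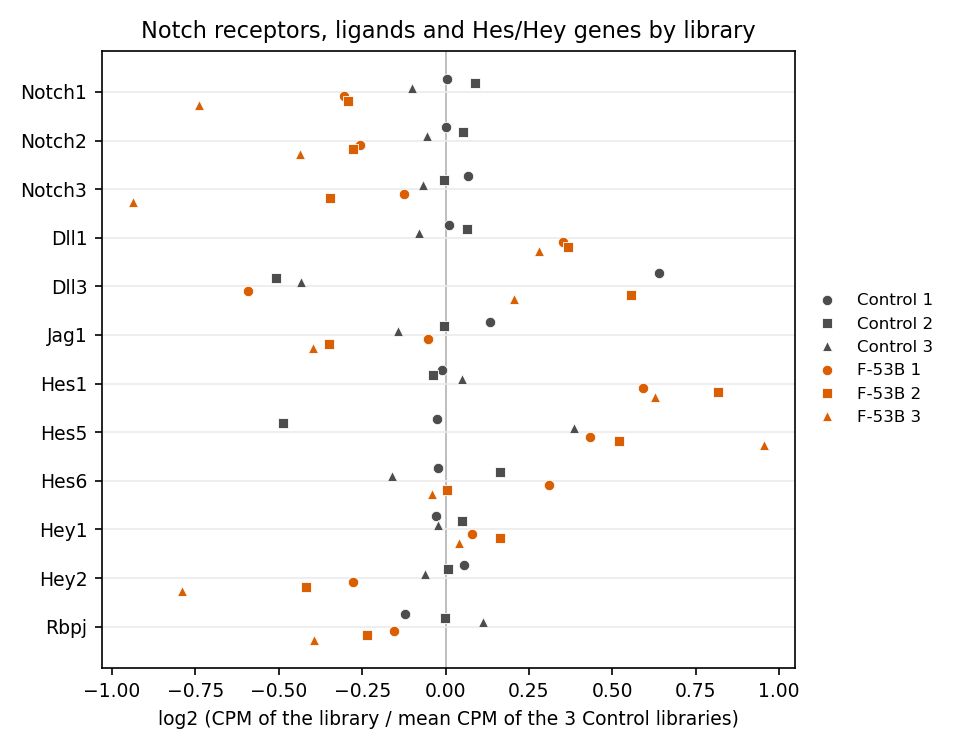
Log2 ratio of each library's CPM to the mean CPM of the 3 Control libraries for 12 Notch and Hes genes, a point per library (grey, Control; orange, F-53B; shape, replicate number). Hes1, the only gene of the 12 past the test, lies higher in all 3 F-53B libraries (8.25 CPM on average against 5.14 CPM), and Notch1 lies lower in all 3 without passing.

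Astrocyte genes were lower in F-53B as a group. Of 20 tested astrocyte markers, 0 rose, 7 fell and 13 did not pass, and adjusted over the list alone 12 fell. In all, 19 of 20 fold changes lay below 0 with a median of -0.37 (camera adjusted p = 1.65e-10; adjusted p = 0.592 with an estimated correlation). Glul fell as above, and Fgfr3 fell from 63.9 to 40.1 CPM (-0.67). The glycolytic enzyme Aldoc fell from 515 to 369 CPM (-0.48) and the gap junction protein Gjb6 from 30.5 to 16.5 CPM (-0.89). Members that did not pass include the water channel Aqp4, at 0.02, and the filament protein Gfap, at -0.12, both chosen after their values were seen. The list scores were 0.07, 0.00 and -0.05 in the Control libraries and -0.31, -0.31 and -0.51 in the F-53B libraries (exact permutation p = 0.1, the smallest possible). The number of members that fell was 3, 3 and 4 without Control replicates 1, 2 and 3, 10 without F-53B replicate 1 and 2 without F-53B replicate 2. It was 11 with DESeq2 or the exact test of edgeR, 12 with no filter, 1, 0 and 0 in the limma fits of RPKM values with a pseudocount of 0.1, of 1 and of 0.1 with no filter, and 3 with the choroid plexus or thalamus score as a covariate. Of 16 oligodendrocyte precursor genes, 1 fell (the receptor Pdgfra, -0.62, adjusted p = 0.0176) and 15 did not pass, against 4 lower adjusted over the list alone. Vcan, Ptprz1 and Cspg4 had -0.52, -0.30 and -0.40 (camera adjusted p = 0.000251; adjusted p = 0.592 with an estimated correlation). Without Control replicate 2 the calls of Aldoc (0.0554) and Pdgfra (0.0809) were lost, without Control replicate 1 that of Gjb6 (0.0582), and without Control replicate 3 those of Gjb6 (0.06) and Pdgfra (0.0919). Without F-53B replicate 2 all 3 were lost (0.0998, 0.0910 and 0.113 for Aldoc, Pdgfra and Gjb6), and without F-53B replicate 1 the precursor count was 2. The precursor score was -0.09, -0.10 and -0.56 in F-53B replicates 1, 2 and 3, beside myelin scores of 0.30, -0.07 and -0.85 in the same libraries.

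Lists of genes of vessels and of the brain's coverings ranked lower too at the preset correlation, though not with an estimated one. Of 26 endothelial and pericyte genes, 2 fell and 24 did not pass: Slc2a1, the glucose transporter of the blood-brain barrier (-0.75, adjusted p = 0.0221), and Myh11, the smooth muscle myosin (-0.82, adjusted p = 0.0317). Adjusted over the list alone 14 fell, among them the transporters Abcb1a (-0.66) and Slco1a4 (-0.43), and the median was -0.34 (camera adjusted p = 1.52e-08; adjusted p = 0.592 with an estimated correlation). That count of 2 was 0 without Control replicate 1 or 2 or without F-53B replicate 2, 1 without Control replicate 3, and 7 without F-53B replicate 1. Of 25 meningeal and fibroblast genes, 1 rose, 7 fell and 17 did not pass, and adjusted over the list alone 3 rose and 14 fell (median -0.63, camera adjusted p = 4.19e-06; adjusted p = 0.592 with an estimated correlation). The matrix proteins Fmod (-1.28) and Ogn (-1.20) and the retinoic acid synthesis enzyme Aldh1a2 (-0.86) fell, whereas the higher member was Crym, which neurons also express. The count of 7 was 1, 2 and 2 without Control replicates 1, 2 and 3, 11 without F-53B replicate 1 and 0 without F-53B replicate 2. Fmod lost its call without F-53B replicate 2 (0.072), Ogn without Control replicate 1 (0.0778), Control replicate 3 (0.0851) or F-53B replicate 2 (0.111), and Aldh1a2 without Control replicate 1 (0.0986), Control replicate 2 (0.0809) or F-53B replicate 2 (0.164). Of 28 extracellular matrix and perineuronal net genes, Timp3 fell (-0.75, adjusted p = 0.0323; 21.3% of its exonic length is shared with the opposite-strand gene Syn3) and 27 did not pass, with Fn1 at -0.41 and Sparcl1 at -0.37. In this list 6 fell adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.592 with an estimated correlation). Without F-53B replicate 1, 5 matrix genes fell. That list's call was lost without Control replicate 3 (0.0874) and F-53B replicate 3 (0.115), and that of Timp3 without Control replicates 1, 2 and 3 (0.115, 0.103 and 0.132) and F-53B replicate 2 (0.22).

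Choroid plexus genes varied between libraries of a group. Of 25 tested choroid plexus and ependymal genes, 0 passed over all genes and 0 adjusted over the list alone, while all 25 fold changes lay below 0, with a median of -1.03 (camera adjusted p = 1.78e-06; adjusted p = 0.592 with an estimated correlation). The list scores were -0.80, 0.34 and 0.48 in the Control libraries and -0.02, -1.70 and -1.85 in the F-53B libraries (exact permutation p = 0.2). The water channel Aqp1 had -1.39, F5 -1.47, Clic6 -1.51 and the folate receptor Folr1 -1.33, with adjusted p between 0.261 and 0.30. Without F-53B replicate 1, 18 members fell and the median was -1.95. Thalamus and habenula genes, from tissue beside the hippocampus, showed a like split of the F-53B libraries, with scores of 0.18, -0.20 and 0.11 in Control and 0.57, -1.32 and -0.84 in F-53B. Of its 21 tested genes 0 passed, also adjusted over the list alone (Six3 -0.85, Rora -0.36; camera adjusted p = 0.155), but without F-53B replicate 1 the list was lower with 11 members past the threshold (4.22e-10; adjusted p = 0.476 with an estimated correlation). Of 26 oligodendrocyte and myelin genes 0 passed, also adjusted over the list alone, with Enpp2, which the choroid plexus also expresses, at -1.10 and the myelin gene Mobp at -0.42 (camera adjusted p = 0.0743). The myelin list was lower without F-53B replicate 1 (4.86e-06) or 2 (0.0254) and higher without F-53B replicate 3 (0.00998). These 3 calls were lost with an estimated correlation (adjusted p = 0.613, 0.842 and 0.699). With the choroid plexus score as a covariate, added after the data were seen, 5 genes rose and 37 fell, and with the thalamus score 4 rose and 45 fell. With the choroid plexus score the lists of GABA genes (0.131), oligodendrocyte precursors (0.0505), interferon genes (0.147) and matrix genes (0.166) were not called, nor were the matrix genes with the thalamus score (0.0651). The neocortex list, not called without a covariate (0.98), was lower with the choroid plexus score (0.00619, 1 member lower; adjusted p = 0.849 with an estimated correlation).

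**Figure D3:**
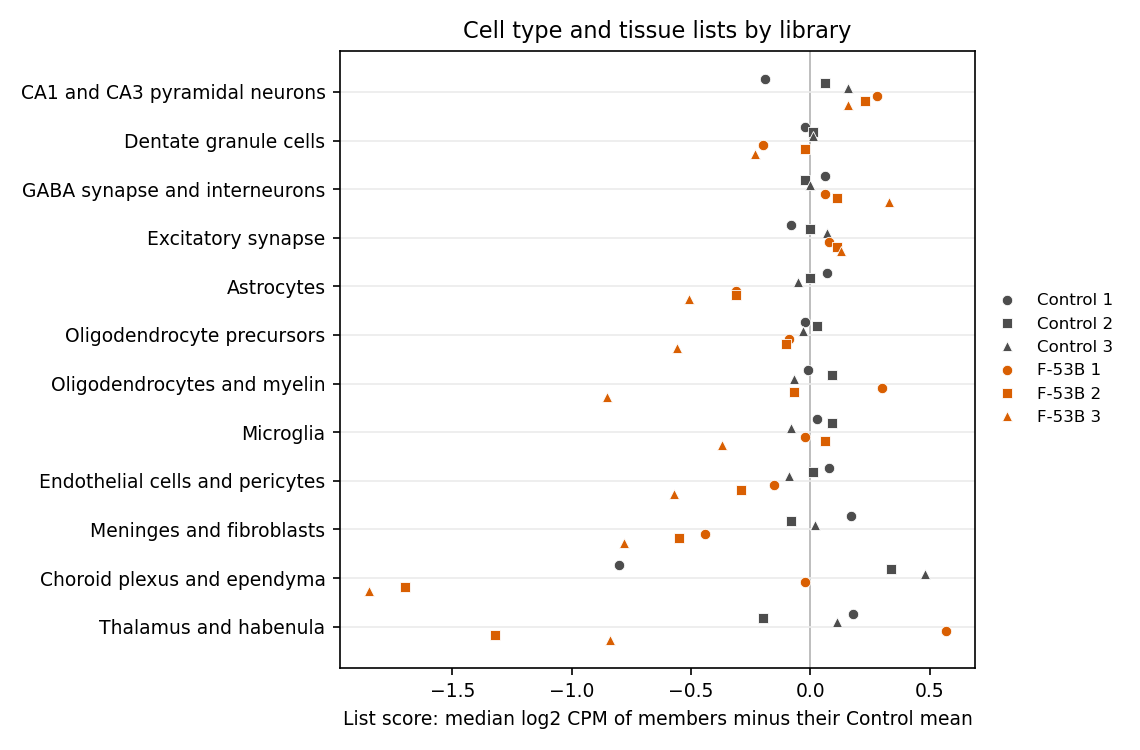
List scores (median over a list's genes of log2 CPM minus the gene's Control mean) of cell type and tissue lists in 3 Control and 3 F-53B hippocampus libraries, a point per library (grey, Control; orange, F-53B; shape, replicate number). Astrocyte scores lie between -0.51 and -0.31 in F-53B and between -0.05 and 0.07 in Control, whereas choroid plexus scores range from -1.85 to -0.02 in F-53B and from -0.80 to 0.48 in Control.

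Among neuronal groups, the lists of GABA synapses, pyramidal neurons, excitatory synapses and channels ranked higher in F-53B at the preset correlation, and those of dentate granule cells and immediate early genes lower. None of these calls held with an estimated correlation. CPM values are relative to a library total. The small rises therefore cannot be told apart from a lower share of the non-neuronal transcripts described above. The same limit holds for the list of oxidative phosphorylation genes given below. Of 32 genes of GABA synapses and interneurons, Cck rose and 31 did not pass. Adjusted over the list alone 6 rose, including Sst (0.55) and Cnr1 (0.41). Fold changes of 24 of 32 lay above 0 (median 0.16, camera adjusted p = 9.91e-05; adjusted p = 0.592 with an estimated correlation). Of 20 pyramidal neuron genes of CA1 and CA3, 0 passed over all genes, and adjusted over the list alone 4 rose and 1 fell. Dkk3 had 0.30, Wfs1 0.52, Fibcd1 0.45 and Coch -0.56 (camera adjusted p = 0.00197; adjusted p = 0.592 with an estimated correlation). Of 46 excitatory synapse genes 0 passed, also adjusted over the list alone, with the vesicle protein Syp at 0.26 (16.8% of its exonic length shared with opposite-strand Gm14703), Nlgn2 at 0.23, Grm5 at 0.26 and Syn2 at 0.20 and a median of 0.10 (camera adjusted p = 0.00197; adjusted p = 0.592 with an estimated correlation). Of 39 voltage-gated channel genes 0 passed, also adjusted over the list alone, with Cacna1b at 0.19, Kcnc2 at 0.23 and Kcnd2 at 0.25 and a median of 0.12 (camera adjusted p = 0.00197; adjusted p = 0.592 with an estimated correlation). Without Control replicate 1 the pyramidal (0.0813) and excitatory synapse (0.0631) lists were not called, and without Control replicate 2 or F-53B replicate 2 Cck was not (0.0521 and 0.0658). Without F-53B replicate 1 the GABA median was 0.25 with 4 genes higher, and without F-53B replicate 3 it was 0.08. Without F-53B replicate 1, 2 pyramidal genes rose, without F-53B replicate 3 1 did, and without Control replicate 1, 2 granule cell genes fell. Of 20 dentate granule cell genes, Pdzd2 fell and 19 did not pass, against 2 higher and 6 lower adjusted over the list alone. The granule cell factor Prox1 had -0.28, Tdo2 -0.52 and Dsp -0.38 (camera adjusted p = 0.0128; adjusted p = 0.592 with an estimated correlation). Of 28 immediate early genes 0 passed, and adjusted over the list alone 1 fell, Klf4 (-0.77). Bdnf had -0.31, Egr2 -1.01 and Per1 -0.36 (camera adjusted p = 0.0128; adjusted p = 0.747 with an estimated correlation). The granule cell call was lost without F-53B replicate 1 (0.0977) or 3 (0.0693), and the immediate early call without Control replicate 3 (0.491) or F-53B replicate 1 (0.0602). Of 47 autism-associated genes 0 passed, also adjusted over the list alone, with Cntnap2 at 0.30, a median of -0.04 and a mean of 0.00 (camera adjusted p = 0.994).

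Hormone and metabolic groups included further calls. Of 20 glucocorticoid responsive genes, 5 fell and 15 did not pass, and adjusted over the list alone 1 rose and 10 fell (median -0.40, camera adjusted p = 5.18e-07; adjusted p = 0.592 with an estimated correlation). Mt2 and Sult1a1 fell as above, Plin4, a lipid droplet coat protein, fell from 3.41 to 0.638 CPM (-2.40), and Tsc22d3, the leucine zipper protein induced by glucocorticoids, from 57.5 to 32.0 CPM (-0.84). The count of 5 was 3 without Control replicate 1 or 3 and 2 without F-53B replicate 2. It was 8 with DESeq2, 9 with the exact test of edgeR, 10 with no filter, 2, 2 and 1 in the same RPKM fits, 2 with the choroid plexus score and 3 with the thalamus score. Of 26 PPAR-alpha target genes, Plin4 fell and 25 did not pass, and adjusted over the list alone 1 rose and 9 fell. Angptl4 stood at -1.02 and Pdk4 at -0.57 (camera adjusted p = 9.91e-05; adjusted p = 0.592 with an estimated correlation). Of 23 thyroid hormone responsive genes, Dio2, the deiodinase that activates thyroxine, fell from 131 to 69.0 CPM (-0.93, adjusted p = 0.0288), and adjusted over the list alone 1 rose, Nrgn (0.34), and 4 fell. Thrsp had -0.31 and Aldh1a1 -0.62 (camera adjusted p = 0.274). Of 45 nuclear-encoded genes of oxidative phosphorylation, 0 passed, also adjusted over the list alone but 39 fold changes lay above 0. Ndufs3 stood at 0.26, Cox5b at 0.25, Ndufb3 at 0.29 and Ndufa8 at 0.24 (median 0.10, camera adjusted p = 1.47e-05; adjusted p = 0.592 with an estimated correlation). Of 24 interferon and inflammatory genes, Lgals3bp fell (-0.92, adjusted p = 0.0372) and 23 did not pass, against 1 higher and 6 lower adjusted over the list alone. Bst2 had -0.84, Tnfaip3 0.53 and Nfkbia -0.45 (camera adjusted p = 0.00138; adjusted p = 0.592 with an estimated correlation). Of 24 NRF2 and oxidative stress genes, Mt2 and the related Mt1 (-0.74, adjusted p = 0.0486) fell, and 5 did so adjusted over the list alone, with Gstm1 at -0.29 and Slc7a11 at -0.39 (camera adjusted p = 0.064). Without F-53B replicate 1, 4 PPAR-alpha and 3 interferon genes fell. Plin4 lost its call without F-53B replicate 2 (0.0642), Tsc22d3 without Control replicate 1 (0.0938), Control replicate 3 (0.0919) or F-53B replicate 2 (0.154), and Dio2 without Control replicate 1 (0.10) or F-53B replicate 2 (0.157). Mt1 and Lgals3bp kept theirs only without F-53B replicate 1 (0.0183 and 0.00442), the others giving 0.059 to 0.226. The thyroid list was lower without F-53B replicate 1, with 4 members lower (0.0364; adjusted p = 0.476 with an estimated correlation). So was the NRF2 list without Control replicate 3 (0.0375) or F-53B replicate 1 (0.0141), or with a filter at a mean CPM of 1 (0.0286). Its calls were lost with an estimated correlation (adjusted p = 0.746, 0.579 and 0.564).

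In all, camera called 5 lists higher and 11 lower of 34 with its preset correlation, and 0 of the 34 held with an estimated one. By fry, 0 lists moved on balance in 1 direction past the threshold, the smallest adjusted p being 0.0883, and 22 held genes that changed in either direction. A change of scaling to RLE size factors or library totals moved the median of all genes by at most 0.003 log2 units.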

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

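The choroid plexus and thalamus scores as covariates, and estimated correlations in the refits, were chosen after the data were seen. Against 155 genes (17 higher, 138 lower), counts were within 1.5-fold with limma-voom, RLE size factors, library totals and a filter at a mean CPM of 1. They were 622 (208 higher, 414 lower) with DESeq2, 614 (162, 452) with the exact test, 1154 (353, 801) with no filter, 23 (4, 19) on log2(RPKM + 0.1), 15 (3, 12) on log2(RPKM + 1), 10 (2, 8) on RPKM with no filter, 410 (103, 307) at an adjusted p under 0.1, 47 (1, 46) with a change of at least 1 log2 unit as well, and 259 (49, 210) at an unadjusted p with that change. With the choroid plexus score they were 42 (5, 37) and with the thalamus score 49 (4, 45). Leaving out 1 library gave 21 to 448 genes, 1 to 59 higher and 20 to 389 lower; F-53B replicate 2 gave the lowest total and F-53B replicate 1 the highest. Of the 155 genes, 149 were called by DESeq2, 155 by the exact test, 141 by limma-voom, 31 with the choroid plexus score and 46 with the thalamus score. All 155 kept their sign in each, although non-overlapping groups left little room for another sign without a covariate. The cause of the differing counts was not tested.

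The set tests gave 16 lists, 0 with an estimated correlation or fry, 15 to 20 when a library was left out, 12 with the choroid plexus score and 21 on limma-voom values; the other alternatives gave 15 to 20. For the Notch list camera adjusted p ranged from 0.159 to 0.343 over the leave-outs and for the Hes and Hey list from 0.371 to 0.989. Of 39 named genes that were called, 14 were called without each of the 6 libraries, 1 higher and 13 lower. Dll3 turned to -0.11 without Control replicate 2, -0.06 without Control replicate 3, -0.17 without F-53B replicate 2, -0.67 with the choroid plexus score and -0.23 with the thalamus score, and Hes6 to -0.02 without F-53B replicate 1; neither was called, and their leave-outs reached 0.59 and 0.19. The call for Hes1 was also lost with either score (adjusted p = 0.135 and 0.111), with the replicate number as a block and on RPKM, over a range of 0.52 to 0.73 in fold change.

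With the replicate number as a block, 38 genes passed (2 higher, 36 lower), 34 of them among the 155; the microglia (0.0311) and myelin (0.0402) lists gained a camera call and the matrix list lost it (0.0507). With an estimated correlation the block gave adjusted p = 0.741 for microglia and 0.84 for myelin, so neither was called. With the block 3 astrocyte and 2 glucocorticoid responsive genes fell. The values showed no pairing by number: deviations of libraries sharing a number correlated at -0.063, 0.007 and -0.006, none over 0.1, and not every library correlated best with its own number. Deviations from a mean of 3 libraries sum to 0, so this check cannot exclude a pairing, which the labels leave open. The 10 splits of the 6 libraries are too few for a share under 0.05; 1 of 10, the real one, gave 155 genes, and the highest of the others gave 4. The lower astrocyte median (-0.37) was -0.31 with the choroid plexus score (camera adjusted p = 5.85e-06; adjusted p = 0.849 with an estimated correlation). F-53B replicate 1 had a choroid plexus score of -0.02 with an astrocyte score of -0.31, and Control replicate 1 had -0.80 with 0.07. At the preset correlation this argues against that tissue as the whole cause. Of 10000 random lists matched on GC content, length and expression, 0% had a median as low, the lowest being -0.13, which argues against those properties. Small changes can be missed: 14% of simulated 1.3-fold changes in genes of at least 50 counts were found. A gene under 3 counts in a library lies below 0.0531 to 0.0762 CPM.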

Other observations

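The tests below of equal lowering over astrocyte genes, of microglia against astrocytes, of the glucocorticoid list, of Ttr, of the thalamus and of estimated correlations in refits were chosen after the result was seen. So were the genes named in the next paragraph. The test of oligodendrocyte precursors was written before its result was seen.

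Some further genes fell in the F-53B libraries, none of them tested as a group. The mannose receptor Mrc1 fell from 5.38 to 2.58 CPM (log2 fold change -1.06, edgeR adjusted p = 0.0119), the hyaluronan receptor Lyve1 from 3.62 to 1.32 CPM (-1.44, adjusted p = 0.0345) and the coagulation factor F13a1 from 3.48 to 1.76 CPM (-0.98, adjusted p = 0.0441). The scavenger receptor Cd163 had -1.28 (adjusted p = 0.0689) and did not pass. Lower genes also included the endothelial Vwf (-0.86, adjusted p = 0.00818), the lipid transporter Mfsd2a (-1.03, adjusted p = 0.00823), elastin Eln (-0.82, adjusted p = 0.0331) and the collagen Col1a2 (-0.89, adjusted p = 0.0436), while the tight junction gene Cldn5 had 0.05 (adjusted p = 0.902). Other lower genes were Txnip (-0.98, adjusted p = 0.00527), Hif3a (-1.57, adjusted p = 0.0075) and Klf15 (-0.61, adjusted p = 0.0461). The glucocorticoid responsive Fkbp5 had -0.21 (adjusted p = 0.451) and the receptor gene Nr3c1 0.02 (adjusted p = 0.948).

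Of the remaining lists, 0 were called by camera. Of 21 microglial genes 0 passed over all genes and 0 adjusted over the list alone, with C1qb at -0.35 and Tmem119 at -0.41 (camera adjusted p = 0.0643); the list was lower without Control replicate 3 (0.012), F-53B replicate 1 (0.0239) or F-53B replicate 2 (0.00271), or with a filter at a mean CPM of 1 (0.0287). These calls were lost with an estimated correlation (adjusted p = 0.813, 0.755, 0.703 and 0.798). Of 25 genes of the unfolded protein and heat shock response 0 passed, and adjusted over the list alone 1 rose and 3 fell, with Asns at 0.31 and Hspa5 at -0.33 (camera adjusted p = 0.0836, and 0.0471 without Control replicate 1; adjusted p = 0.810 there with an estimated correlation). Of 24 cholesterol synthesis genes 0 passed, also adjusted over the list alone, with Lss at -0.19 (camera adjusted p = 0.205, and 0.0174 without F-53B replicate 1; adjusted p = 0.579 there with an estimated correlation). Of 46 ribosomal protein genes 0 passed, also adjusted over the list alone, with Rpl10 at -0.16 and Rpl15 at 0.12 (camera adjusted p = 0.438, and 0.0231 without Control replicate 3; adjusted p = 0.863 there with an estimated correlation). Of 20 neocortical genes 0 passed, and adjusted over the list alone Lmo4 (0.34) rose and Cux1 (-0.34) fell (camera adjusted p = 0.98, and 0.00619 in the downward direction with the choroid plexus score as a covariate; adjusted p = 0.849 there with an estimated correlation). Of 18 striatal genes 0 passed, also adjusted over the list alone, with Foxp1 at 0.28 and Six3 at -0.85 (camera adjusted p = 0.883). Of 18 neuropeptide and hypothalamic or pituitary hormone genes Cck rose (3 genes did without F-53B replicate 1, and 0 without Control replicate 2 or F-53B replicate 2), and adjusted over the list alone 3 rose and 1 fell, with Npy at 0.38 and Pmch at -1.45 (uncertain, with 58.1% of its exonic length shared with opposite-strand Parpbp); median (-0.05) and mean (-0.10) lay below 0 and the test was upward (camera adjusted p = 0.783). Of 11 blood genes 0 passed, and adjusted over the list alone 2 rose, among them S100a9 (1.91, at 0.236 CPM in Control). The median was -0.10, the mean 0.13 and the test upward (camera adjusted p = 0.566). That median lay above 0 without Control replicate 1 (0.07), Control replicate 2 (0.04) or F-53B replicate 3 (0.09), and below 0 without each of the others. Of 14 mitochondrially encoded genes 0 passed, also adjusted over the list alone, with mt-Rnr1 at -0.24 and mt-Co1 at -0.26; the median was -0.19, the mean 0.19 and the test downward (camera adjusted p = 0.132, and 0.0185 with a filter at a mean CPM of 1; adjusted p = 0.564 there with an estimated correlation). Without F-53B replicate 3 the median of that list was -0.06. In that list mt-Co2, mt-Co3 and mt-Atp6 were counted at 0.17, 0.325 and 0.369 CPM in Control while mt-Co1 stood at 7090 CPM, so the fold changes of those 3 genes are uncertain.

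The lower astrocyte genes have several candidate explanations. An even loss of astrocytes would lower all their transcripts alike, but 12 genes largely restricted to astrocytes differed from a common change (chi-square test of Cochran's Q = 59.7, p = 1.06e-08), with Aqp4 at 0.02 and Gjb6 at -0.89, which argues against an even loss as the whole cause. The test takes genes as independent and their standard errors as known, and it does not bear on an uneven loss. A smaller share of all non-neuronal cells would lower microglia as much, yet the microglia score minus the astrocyte score was higher in F-53B by 0.27 ± 0.08 (SE over libraries), although endothelial (-0.15, -0.29 and -0.57) and meningeal scores (-0.44, -0.55 and -0.78) were low in the 3 F-53B libraries too, so a lower share of some non-neuronal types stays open. Lower glucocorticoid signalling, or another hour of sampling, may lie behind part of it: the glucocorticoid list was lower with camera adjusted p = 5.18e-07. With an estimated correlation its unadjusted camera p was 0.0687, and that of the astrocyte list itself was 0.0762. No label gives the hour, so this explanation cannot be told apart from an effect of the compound. An effect of F-53B on astrocyte transcription stays open as a hypothesis.

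The choroid plexus genes differed between libraries of a group, and choroid plexus tissue in the dissected pieces is a candidate source. Ttr, its most abundant transcript, stood at 878, 2322 and 2523 CPM in the Control libraries and 1524, 293 and 478 CPM in the F-53B libraries. With group means removed, the other list members had a median correlation with Ttr of 0.92 over the 6 libraries, against a 95th percentile of 0.24 for random lists matched on expression, which is consistent with a varying amount of that tissue. Of the 26 list members 25 were counted high enough in these hippocampal libraries to be tested. An effect of F-53B on the choroid plexus itself was not tested.

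Myelin genes stood low in F-53B replicate 3, with a list score of -0.85 and Mobp at 1241 CPM against 2439 to 3212 CPM in the other 5 libraries. Less thalamus and white matter in that piece may be the source: its thalamus score was -0.84, below -0.20 to 0.57 in 4 libraries, but F-53B replicate 2 had a lower one (-1.32) with a myelin score of -0.07, so the values leave this open. Fewer cells of the whole oligodendrocyte lineage may be involved, since the precursor score lay -0.53 from the median of the other libraries and the myelin score -0.84, and these values do not decide it. The low scores were not confined to that lineage. F-53B replicate 3 also had the lowest microglia (-0.37), endothelial (-0.57), astrocyte (-0.51) and meningeal (-0.78) scores of all libraries, though not the lowest blood score (-0.23). With 1 library of its kind, a difference in dissection and one between animals cannot be told apart.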
